A study of Homo sapiens with 2 samples.

How the data were processed

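Gene expression was measured on 2 Affymetrix arrays of SKOV3 cells, an established human ovarian carcinoma line. Both samples came from 1 MED12-knockout clone. One carried the vector and the other had MED12 put back (rescued cells). MED12 encodes a subunit of the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. Per the labels' protocols, cells were grown with 10% fetal bovine serum at 37 °C and 5% CO2, total RNA was purified on columns, and biotin-labelled cRNA was made from 100 ng of it. The labels give 1 array per group, so no test between the groups, SD or p-value was possible, and p-values and paired fits are not given.

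The values are MAS5 signals per probe set on a linear scale, as deposited by the authors. MAS5 is named in the submitters' processing notes, and its version, its scaling target and its detection calls are not given in the sources used here. MAS5 summarises the probe pairs of a probe set into 1 signal, and its low signals are noisy. The table has 54675 rows, of which 62 are control probe sets and 1 has no value, which left 54612 probe sets with a signal on both arrays. Both columns carry the identity of their sample, and no other column of sample values was present. The arrays have no sequencing depth, and their number limits the precision.

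The names of the probe sets were checked against the values before any gene was named. Gene symbols came from a platform annotation that lists 42898 of the probe sets. Of these, 41097 have 1 symbol and 1801 have several, and 11777 rows of the table are not in it. Symbols were brought up to date through their gene identifiers, which changed 0 of them. The checks were the order of the rows, the signals of the manufacturer's control probe sets, the correlation of log2 signals between 2 probe sets of a gene, the same correlation after shuffles of the values over the whole table or within 200 rows, and the median signal of gene lists against 10000 random lists of rows of the same size. These checks failed for all but the control probe sets, as the results describe. Values were therefore analysed per probe set without a gene name. The planned values for MED12, EGFR, the 31 gene lists and 4 cell type marker lists, the agreement between probe sets and the rule for named genes (the largest differences measured on both arrays, the largest lower bounds, and list members) rest on those names and are not given. Matching values to genes by row position was not attempted.

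The difference between the arrays was log2 of the rescued signal minus log2 of the vector signal, at the scaling of the deposited values. Signals under a floor were raised to it. The floor was the mean of the medians of the 2 arrays over probe sets other than controls. A probe set was measured if it reached the floor on at least 1 array, and where it lay under the floor on the other array its difference is a lower bound. Probe sets with a difference of 2-fold or more were counted in each direction. The counting was tested on simulated data with 200 changed probe sets among 54612 and noise as between the spiked controls. It counted 100% of those changed 3-fold, 4-fold or 8-fold in the right direction and 0% of those changed 1.5-fold. This tests the arithmetic only, since the noise was far smaller than the changes, and gives no rate of false counts between cultures. In a simulated table with right names the correlation between 2 probe sets of a gene was 0.66, and it was 0.007 after the rows had been sorted by fold class. Both values follow from the variation chosen for the simulation, which was not fitted to these arrays. A shift of 500 rows put into the names was found.

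The groups, the floor, the threshold, the gene lists and the first set of alternatives were fixed before the data were examined. The alternatives were 3 other scalings, other floors, pseudocounts of 1 and 32, and thresholds of 1.5-fold, 3-fold and 4-fold. Scaling on all spiked controls, on the poly-A controls or on the hybridization controls, and counts within parts of the table were added after seeing the data. Intervals on shares of probe sets are 95% Wilson intervals, which cover counting error only and treat probe sets as independent, which they are not. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with matplotlib 3.10.9 for the figures.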

Results

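Transcript levels were compared between SKOV3 ovarian carcinoma cells labelled as without and with MED12. The comparison set 1 array of a MED12-knockout clone carrying vector against 1 array of the same clone with MED12 restored. Loss and return of MED12 rest on the labels, since no MED12 value could be assigned. The median signal of the 54612 probe sets was 37.1 units on the vector array and 35.3 units on the rescued array. The 95th percentiles were 631 and 680 units, and 1473 and 1611 probe sets exceeded 1000 units. The mean signal after removal of the lowest and highest 2% of probe sets was 106 units on the vector array and 112 units on the rescued array. Each group had 1 array, so no difference below has a replicate check.

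Among the manufacturer's control probe sets for human transcripts, GAPDH, a glycolytic enzyme, had nearly equal signals on both arrays, while ACTB, cytoplasmic beta-actin, and part of the ribosomal RNA had higher signals in the rescued cells. The annotation names GAPDH and ACTB, whereas 18S and 28S rRNA, ISGF3A and Alu are named here from the manufacturer's usual control names alone. The 3 GAPDH control probe sets read 3326 to 3813 units in vector cells, and their log2 differences (rescued minus vector) were 0.14 for the 3′ probe set, 0.05 for the middle one and 0.03 for the 5′ one. The ACTB control probe sets read 3114 units (3′), 983 units (middle) and 491 units (5′) in vector cells, against 4175, 1823 and 611 units in rescued cells. These are log2 differences of 0.42, 0.89 and 0.31. The 3′ control probe set of ISGF3A, the interferon-responsive signalling factor, read 204 units in vector cells and 171 units in rescued cells, a log2 difference of -0.26, and the other 3 ISGF3A probe sets lay under the floor of 36.2 units on both arrays.

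Ribosomal RNA controls differed by probe set. For 18S rRNA, the 5′ probe set read 256 units in vector cells and 644 units in rescued cells, which is 2.52-fold higher, and the middle one read 207 and 496 units, 2.39-fold higher. The 3′ probe set of 18S rRNA read 605 units in vector cells and 586 units in rescued cells. For 28S rRNA, the 5′ probe set was 1.95-fold higher in rescued cells, at 1159 against 593 units, and the middle one 1.38-fold higher, at 486 against 352 units. The 3′ probe set of 28S rRNA lay under the floor on both arrays, at 15.5 units in vector cells and 20.5 units in rescued cells. The probe set for Alu repeats, the brightest on both arrays, read 6457 units in vector cells and 7030 units in rescued cells.

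Bacterial and phage transcripts added during labelling and hybridization gave a spread between probe sets on this pair of arrays, which is not a replicate error. Over the 26 spiked control probe sets above the floor on both arrays, the median log2 difference was 0.08 with an SD of 0.08 between probe sets. Their range was -0.07 to 0.23, and 0 reached 2-fold. A bioB probe set that read 74.7 units on the vector array and 7.26 units on the rescued array, below the floor, was left out of these 26, and its rescued value was printed in another format than the other controls. A lys probe set under the floor on the vector array was left out as well, at 31.9 units there and 39.6 units on the rescued array, a log2 difference of 0.31. The spread of the 26 covers hybridization, scanning and, for the poly-A controls, labelling, and does not cover differences between cultures or RNA preparations. The differences of all 3 ACTB probe sets, and of the 5′ and middle 18S and 28S ones, lay above the highest of these 26 controls. That of the 3′ ISGF3A probe set lay below the lowest of the 26, from which the bioB probe set had been left out. The ratio of the 3′ to the 5′ signal, a measure of RNA integrity, was 6.34 for ACTB in vector cells and 6.83 in rescued cells, and 1.03 and 1.11 for GAPDH.

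**Figure D1:**
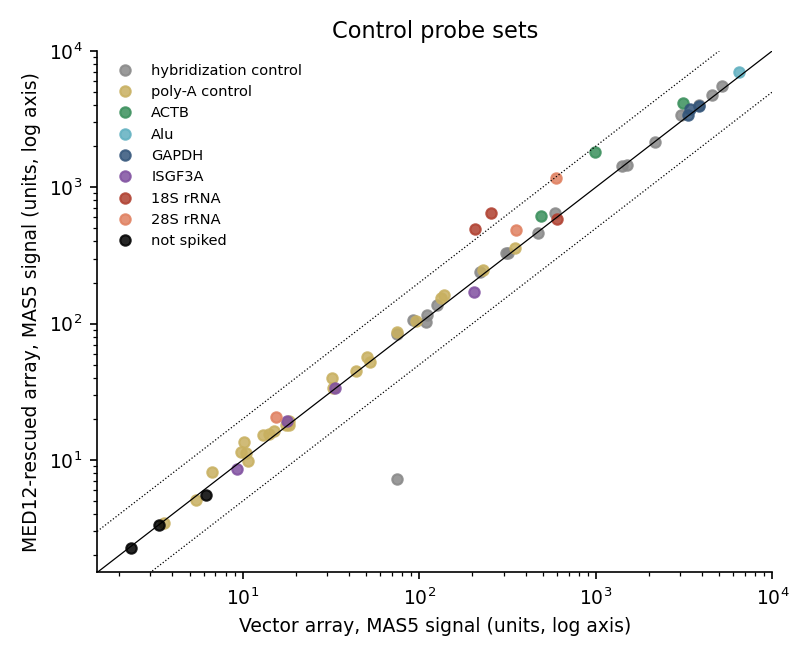
Signals of the 62 control probe sets on the vector array (x axis) and the MED12-rescued array (y axis), in MAS5 units on log axes, 1 point per probe set, with lines at equality (solid) and 2-fold (dotted). The spiked controls and GAPDH lie along the line of equality, the 5′ and middle 18S rRNA probe sets lie above the upper 2-fold line at 2.52-fold and 2.39-fold, and 1 bioB probe set lies far below it at 74.7 against 7.26 units.

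At the deposited scaling, more signals were 2-fold higher than 2-fold lower in rescued cells, but this order turned with the scaling. Of 30472 probe sets that reached the floor on at least 1 array, 2678 were at least 2-fold higher in rescued cells and 1860 at least 2-fold lower, together 14.9% of those measured. Higher signals made up 59.0% of the 4538 (95% Wilson interval 57.6% to 60.4%). Centred on all spiked controls, 2344 were higher and 2110 lower, a share of 52.6%. Centred on the poly-A controls alone, which moved the median log2 difference from -0.01 to -0.12, 2153 were higher and 2326 lower, a share of 48.1%. With no floor and 1 unit added to each signal, 3342 were higher and 3139 lower, a share of 51.6%. Among the 24143 probe sets above the floor on both arrays, 2012 were 2-fold higher with a median fold of 2.52, and 1245 were 2-fold lower with a median fold of 2.56. A further 666 higher and 615 lower differences were lower bounds, because the other array was under the floor. At 4-fold, 596 probe sets were higher and 421 lower, and at 8-fold, 200 were higher and 130 lower.

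At the deposited scaling the differences between the arrays were centred close to equality, but they spread more widely than those of the spiked controls. Among probe sets above the floor on both arrays the median log2 difference was -0.01, 67.7% of them differed by less than 1.5-fold, and the correlation of log2 signals across probe sets was 0.89. The SD of the log2 difference was 0.73, against 0.08 for the spiked controls, whose spread does not cover cultures or RNA preparations. With these probe sets parted by mean signal into 4 groups of equal size, differences of 2-fold made up 21.2% of the group between 125 and 302 units and 13.6% of the brightest group. The floor itself limits the differences that the dimmer groups can show. Between 125 and 302 units, 837 probe sets were higher in rescued cells and 441 lower. The centre moved with signal: from the dimmest group to the brightest, the median log2 differences were -0.09, -0.05, 0.10 and 0.06.

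These counts could not be assigned to genes, because the names in the table did not go with the values outside the control probe sets. The names ran in alphabetical order, with 0 out of place, whereas the values ran in stretches set mostly by the difference between the arrays. With a tolerance of 0.001 on the fold, the first 3207 rows were all at least 2-fold higher in rescued cells and the next 2696 rows all at least 2-fold lower. Without the tolerance, 1 of these 5903 rows lay just under 2-fold. A row without values followed, and then 48709 rows with a median log2 difference of -0.07. Of these last rows, 1056 (2.17%) differed by 2-fold or more before any floor was set, and the median of their brighter signal was 20.4 units. In 330 of the 1056 the brighter signal was at or over the floor, so the difference alone did not set the order.

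**Figure D2:**
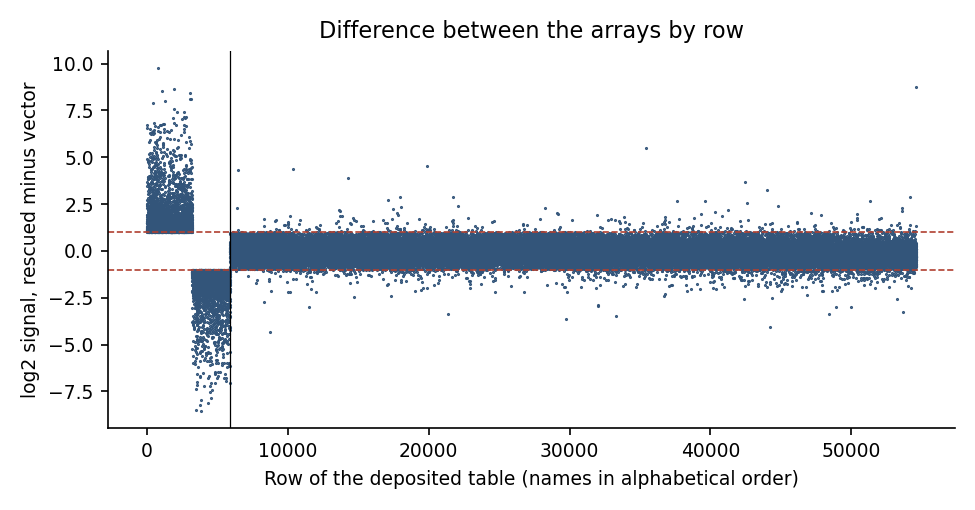
Log2 signal of the rescued array minus that of the vector array (y axis) against the row of the deposited table (x axis), 1 point per probe set other than controls, with dashed lines at 2-fold and a vertical line at the row without values. The 3207 rows at the left lie above the upper dashed line, the next 2696 below the lower one, and the rest mostly between them, although the names beside the rows are alphabetical.

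Signals under the printed names did not correspond to known transcript abundance. The 3 rows named ACTB outside the controls read 22.1 to 35.7 units in vector cells, while the ACTB control probe sets read 491 to 3114 units. The 3 rows named GAPDH read 14.4 to 355 units, against 3326 to 3813 units for the GAPDH controls. Rows named for ribosomal proteins, which are among the most abundant transcripts of a growing cell, had a median of 32.2 units, at the 31.6th percentile of random lists. Rows named for olfactory receptors, which carcinoma cells are not expected to use, had a median of 54.8 units, at the 99.3rd percentile. Oxidative phosphorylation and housekeeping names lay at the 29.1st and 61.3rd percentiles. Of the 35 lists fixed in advance, 3 had a median signal above the central 95% of random lists and 0 below it; these were the names for ERK pathway output, extracellular matrix and integrins, and erythroid and serum-borne markers. Over 10523 genes with 2 or more named probe sets, the correlation of log2 vector signals between 2 probe sets of the same gene was 0.14 across genes, which are not independent replicates. It was 0.16 for rescued signals and 0.27 for the log2 difference. In 1000 shuffles of the values it was 0.04 at most for vector signals and for the log2 difference. A simulated table gave 0.66 with right names and 0.007 after sorting by fold class, but its variation was chosen and not fitted to these arrays. Its signals were also independent of the fold, so neither value sets a scale for the observed ones. Values were also shuffled only within stretches of 200 rows. This kept the runs except in stretches that crossed a border between runs, where rows of different runs were mixed. The highest correlation in 1000 of these shuffles was 0.134 for vector signals, 0.166 for rescued signals and 0.2704 for the log2 difference. The observed values of 0.140 for vector signals and 0.2707 for the log2 difference exceeded all of these shuffles, the latter narrowly, and that of 0.160 for rescued signals exceeded the upper limit of their central 95%, 0.155. Such shuffles also remove any order of the values finer than 200 rows, and the 2 probe sets of a gene can lie in neighbouring rows. The excess therefore does not tell a link between names and values from likeness of neighbouring rows. For the log2 difference, the mixing across run borders can also have lowered the shuffled values. Over the 8073 genes with both probe sets after the row without values, the correlation of the log2 difference was 0.01 and that of vector signals 0.13. No value for MED12, for EGFR or for any gene list is therefore given.

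**Figure D3:**
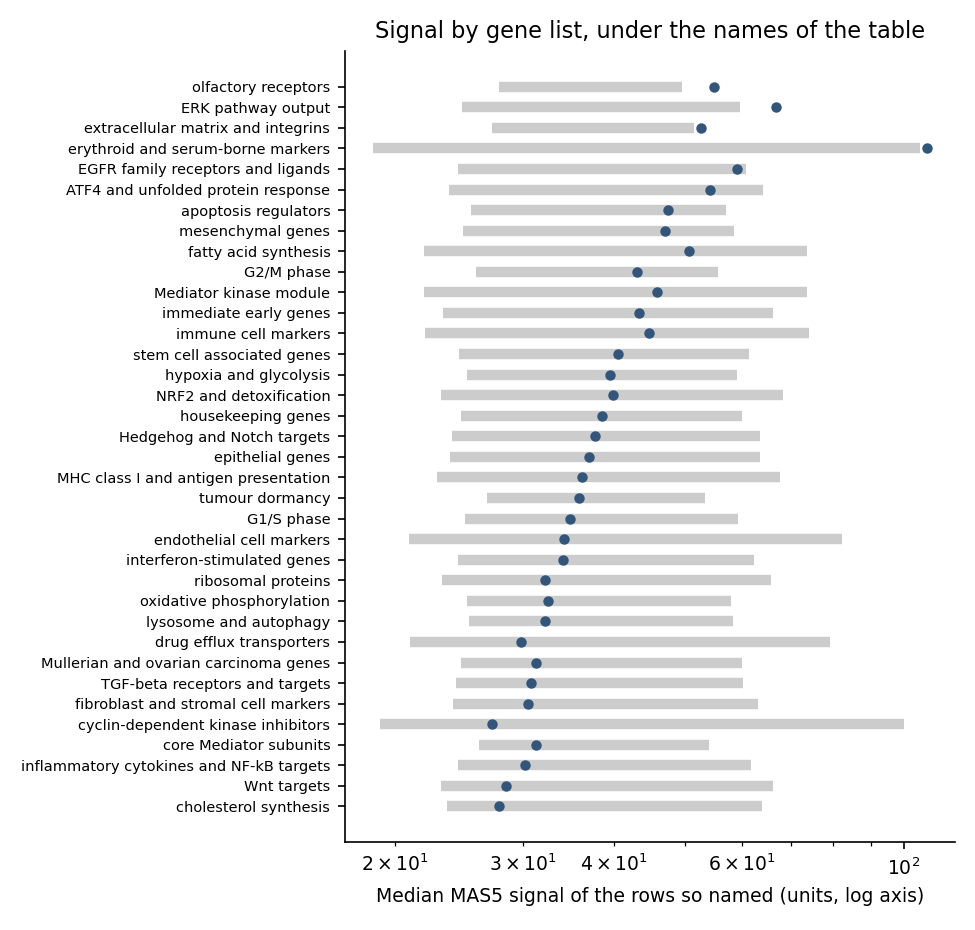
Median MAS5 signal over both arrays (x axis, log scale, units) of the rows named for each of the 35 gene lists and for olfactory receptors (y axis), as points, with grey bars for the central 95% of 10000 random lists of the same size. Ribosomal protein names, at 32.2 units, lie below olfactory receptor names, at 54.8 units.

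The names of the control probe sets did go with their values. The hybridization controls are added in increasing amounts, and in vector cells their geometric mean signals were 101 units for bioB, 318 for bioC, 1273 for bioD and 4083 for cre. The poly-A controls likewise followed their order, with 3′ signals of 37.4 units for lys, 51.7 for phe, 100.2 for thr and 283 for dap, and the trp control, which is not spiked, read 3.63 units. The rescued array gave the same orders. An exception was 1 bioB probe set, which read 74.7 units on the vector array and 7.26 units on the rescued array. The remaining 61 control probe sets were printed to more than 2 decimals on both arrays, as was 0 of the other probe sets, and the rescued value of the exception was printed to 2 decimals.

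**Figure D4:**
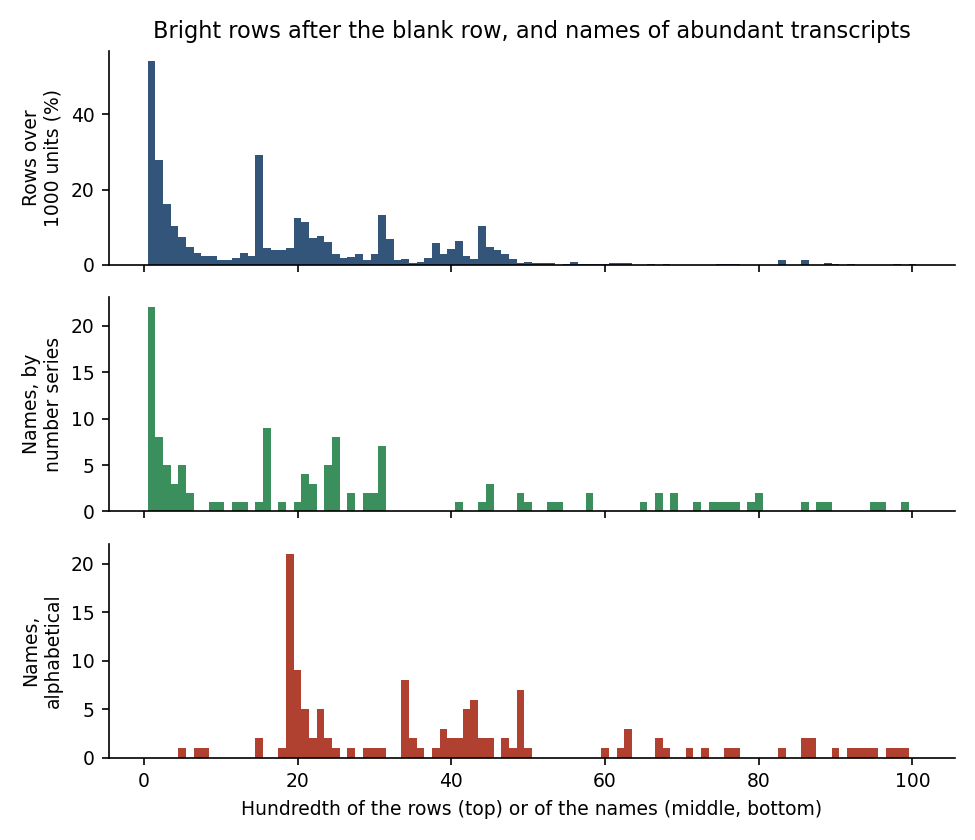
Percentage of rows over 1000 units on either array in each hundredth of the rows after the row without values (top), and number of names of ribosomal protein, oxidative phosphorylation and housekeeping genes in each hundredth of the names, ordered by number series (middle) or alphabetically (bottom). The number series order took the shortest numbers first, then the main series of the array, its latest series of long numbers, and the remaining numbers last. In the first hundredth, 54.2% of rows were bright, and it held 22 of these names in the number series order and 0 in the alphabetical order.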

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

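The tests of this part were chosen after the control signals had been seen. Each signal below belongs to a control probe set outside the counts of 2-fold differences and was picked out because its difference from the vector array, after subtraction of the median of the spiked controls, exceeded 3 SD of those controls (0.25 on the log2 scale) in either direction. Of 13 human control probe sets above the floor on at least 1 array, 7 met this, 6 of them higher and 1 lower in the rescued array. All rest on 1 array per group.

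The 18S rRNA 5′ and middle probe sets were higher in the rescued array by 1.33 and 1.26 on the log2 scale, the 28S rRNA 5′ and middle ones by 0.97 and 0.47, and the ACTB middle and 3′ ones by 0.89 and 0.42. The ISGF3A 3′ probe set was lower, with a log2 difference of -0.26. For the 6 higher ones, a difference in scaling between the arrays is argued against, since the highest of the 26 spiked controls differed by 0.23. Better kept 5′ ends in the rescued sample is argued against for ACTB and GAPDH only. Their 5′ to 3′ ratios changed by -0.11 (SD 0.12 from the spiked controls), where a rise of about 0.97 or more was set as needed. That limit was the difference of single rRNA 5′ probe sets and not a ratio, so the test does not decide the question for rRNA. Nor does it cover the ACTB middle probe set, which differed more than the 3′ one (0.89 against 0.42). A different carry-over or internal priming of ribosomal RNA in the labelling may account for the rRNA part and stays open, as does an effect of MED12 on either RNA, which was not tested because each group has 1 array.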

How the results depend on the processing

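No paired analysis was possible because each group has 1 array. Of 45 counts under 15 alternatives, 29 stayed within 1.5 times the main counts of 4538 probe sets (2678 higher, 1860 lower), and those under median centring, quantile normalization, the loess and the 3 scalings on spiked controls (all, poly-A, hybridization) were all among them. Higher differences made up 59.0% of the main count and outnumbered lower ones under 14 of the 15, from 51.6% with no floor and log2(signal + 1) to 63.3% with the floor at the 75th percentile. Centred on the poly-A controls they were 48.1% (2153 higher, 2326 lower), and on the hybridization controls 53.9%. The higher floor, which leaves fewer probe sets to count, gave 2390 (1514 higher, 876 lower). With no floor and log2(signal + 1), 3139 were lower, since dim probe sets were then counted. The 1.5-fold threshold gave 9886 (5447 higher, 4439 lower), 3-fold gave 1766 (1021 and 745), and 4-fold gave 1017 (596 and 421). A change of threshold moves these counts by definition, so 29 of 45 is not a rate of robustness. After the row without values, the count was 139 (74 higher, 65 lower). The interval of the share of higher ones there, 45.0% to 61.3%, includes an even split. The rows had already been parted by fold, so the counts by part of the table do not test the processing, although the 15 alternatives include them. The counts by part of the table and the spiked-control scalings were chosen after seeing the data. The olfactory receptor floor, the rules for several probe sets of a gene, and all alternatives for MED12, EGFR, the gene lists and named genes were not run, because they need gene names. Low signals limit the counts: 24143 of 54612 probe sets were above the floor on both arrays.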

Other observations

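The tests of a constant shift of the names, of low signals and of scaling by median centring, quantile normalization and the loess were written before their results were seen, and the 3 scalings on spiked controls and the other tests of this part were chosen after.

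The mismatch of names and values may have arisen when the rows were sorted by the difference between the arrays and names in another order were then set beside them. In favour of this, the first 2 runs each showed brighter rows where 125 names of ribosomal protein, oxidative phosphorylation and housekeeping genes would fall if names were ordered by number series: the mean log2 signal there was 8.29 in the first run and 7.85 in the second, above the central 95% of random names (upper limits 7.74 and 7.18), and in alphabetical order it was 7.52 and 7.06. Within the run that follows the row without values, 16.0% of rows exceeded 1000 units around the relative place of the same names in that order, against a median of 3.24% for random names and 3.92% in alphabetical order. The random names were drawn singly from the whole order, whereas 22 of the 125 names fell in its first hundredth, where 54.2% of rows were bright. The comparisons with random names therefore treat clustered names as independent. That the names are right is argued against. The rows named ACTB and GAPDH lay far under the control probe sets of these genes (log2 difference -6.61), which cells with right names would not show. Over 54612 constant shifts of the names, the highest correlation between probe sets of one gene was 0.21, at 2170 rows, against 0.14 with no shift. This was under the 0.5 set as the limit. The correlation that right names would give on these arrays was not measured, so this test does not exclude a constant shift. The relative places fit only on average, so they do not return the name of any one row, and which probe sets were in the first 2 runs stays open.

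The excess of 2-fold higher over 2-fold lower probe sets in rescued cells depends on scaling. Of 6 other scalings, 5 left the share of higher ones between 52.6% and 57.5%, against 59.0% as deposited, and centring on the 9 poly-A controls brought it to 48.1%. Scaling as the whole cause cannot be told apart from a true excess, because the control sets give different factors. Noise of low signals is argued against at the deposited scaling, since the share was 63.3% with the floor at the 75th percentile. No other scaling was run at that floor, where the median log2 difference was 0.06 against -0.01 at the main floor. A difference between single cultures and an effect of MED12 both stay open, since 1 array per group does not separate them.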
